A study of Arabidopsis thaliana with 16 samples.

How the data were processed

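Total RNA of Arabidopsis thaliana was measured on 16 expression arrays, 8 of the wild type (WT) and 8 of the pete1 mutant, which lacks 1 of the plastocyanin isoforms. Plants of both groups were Columbia 0 and grew on soil. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 8 arrays of a group came from separate plants, so p-values measure the spread between these arrays, which may be technical.

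The deposited values are read as spot intensity relative to the brightest spots, on a linear scale from 0 to a ceiling of 100. How the authors scanned and background-corrected the arrays, the details of the scaling, and which genome build they used are not given in the sources used here. Each array has 3439 probes, and 1 to 6 values per array lie at the ceiling. Between 454 and 846 values per array are 0, and the array medians run from 0.0524 to 0.205, a 3.91-fold range, so the deposited table was not treated as already normalized. The number of arrays limits the precision.

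Of the 3439 probes, 692 carry 1 gene symbol in the platform annotation, 870 carry several and 1877 carry none. Of the 692, 690 matched a gene of the RefSeq TAIR10.1 table, which was used for names alone. No gene was named from a probe with several symbols. None of the probes with 1 symbol names PETE1 or PETE2, the plastocyanin genes, so the planned tests of these 2 genes were not run and the labels could not be checked against the mutated gene.

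Intensities were quantile-normalized between arrays with limma 3.58.1 in R 4.3.3. Values under the 5th percentile of an array's positive values were set to that percentile, and log2 was taken. Probes were compared with limma's lmFit and eBayes over all 16 arrays, two-sided, without a block, and p-values were adjusted by Benjamini-Hochberg at a threshold of 0.05. Of 22 gene lists with 329 genes, those with 5 or more measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Where a gene has several probes the brightest was used. The 2 probes of AT2G25870, the single gene with more than 1 probe, differ in sign and neither passed the test. The design, the lists and the settings to compare were fixed before the data were examined.

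The named genes follow a fixed rule: the 6 largest rises and the 6 largest falls among probes with 1 gene that passed the test and moved the same way on at least 7 of 8 pete1 arrays, and in each list the 2 members with the smallest p, or 4 in a list that passes. The rule ranks by the fitted change, including changes measured against the floor. No fold is given for SBPASE and PRPS6, which the rule names, because nearly all their values in both groups are at the lowest measurable level.

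Arrays with consecutive replicate numbers (1 and 2, 3 and 4, 5 and 6, 7 and 8) deviate together from their group mean. The correlation of their deviations across probes has a median of 0.439. For other arrays of a group the median is -0.300 and the maximum 0.195. Deviations are taken from the mean of the same 8 arrays, which by itself lowers the correlations between other arrays. By the correlation of deviations the closest array is the consecutive one for 16 of 16 arrays. By Spearman correlation of the values it is so for 14; pete1 replicates 1 and 2 are closer to replicates 3 and 4 (0.799 and 0.796) than to each other (0.786). Averaging such arrays, one of the settings fixed in advance, leaves 4 pair averages per group and is given beside each lead result. Levels are the mean ± SD of 4 pair averages on the log2 scale. The smallest p that an exact permutation test of 4 against 4 can give is 0.0286.

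After quantile normalization the arrays' floors differ, from -7.06 to -4.10 on the log2 scale, because their shares of 0 values differ. An alternative chosen after seeing the data uses the highest of these floors (0.0581 in intensity) on all arrays, where 28.4% of values lie. It is called the common floor, and a fold against a group that lies at it on all arrays is a lower bound.

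The fits were tested on 1 simulated data set with the real probes' means and spreads, in which 200 of 3439 probes were changed. With independent arrays 168 probes were called and 5.36% of these were false. With the correlation of 0.718 estimated for consecutive arrays, the fit over 16 arrays called 253 probes, of which 37.9% were false, and the fit over 8 pair averages called 125, of which 4.80% were false. In the latter fit 4% of changes of 1 on the log2 scale were recovered, 52% of changes of 2, 86% of changes of 3 and 96% of changes of 4. The simulation has no floor and no other structure among arrays.

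Settings compared by design were other normalizations, floors, filters on dim probes, tests, array weights, leaving out each array, the replicate number as a block and averaging agreeing arrays. Those chosen after seeing the data were the common floor, the pairs as a random block, combinations of pair averages with other settings, leaving out pairs or pete1 replicates 1 and 2, a local correction along the probe order and 4 further gene lists.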

Results

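The data are expression arrays of soil-grown Arabidopsis, 8 from WT and 8 from the pete1 mutant, which lacks 1 of the plastocyanin isoforms, the copper proteins that carry electrons to photosystem I. Each array gives the intensity of 3439 probes. Values at 0 made up 13.2% to 24.6% of an array. The comparison asks which transcripts differ in level between the mutant and WT on soil.

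The clearest rise in pete1 was that of AT2G27680, an oxidoreductase of the aldo/keto reductase family. Its deposited WT values are all 0, so the p-values given for it do not measure its spread between WT arrays. It lay at the floor on 8 of 8 WT arrays and was measured on every pete1 array, at -0.85 ± 0.44 (log2, SD, n = 4 pair averages), which is at least 9.55-fold higher against the common floor (limma adjusted p with the common floor = 2.9e-08 over 16 arrays and 0.0059 over 8 pair averages; with the floor of each array 1.5e-08 and 0.00029). AT1G02020, a nitroreductase family gene, fell by 3.89 on the log2 scale, from 0.28 ± 1.19 to -3.61 ± 0.58 (SD, n = 4; limma adjusted p = 5.8e-05 and 0.0094). AT5G05330, an HMG-box gene, fell by 2.78, from -0.96 ± 0.39 to -3.74 ± 0.49 (SD, n = 4; limma adjusted p = 7.8e-06 and 0.0142). Of the 12 genes named as the 6 largest rises and the 6 largest falls, these 3 passed the test over both 16 arrays and 8 pair averages. With the common floor the adjusted p over pair averages was 0.0498 for AT1G02020 and 0.0216 for AT5G05330, but with 1 pair left out as well AT1G02020 lost its call in 7 of 8 fits and AT5G05330 in 5 of 8. With the floor of each array AT5G05330 lost it without pete1 replicates 3 and 4, and on the deposited scale AT5G05330 did not pass over pair averages (adjusted p = 0.0854).

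The other 9 of these genes passed over 16 arrays and did not pass over pair averages. With the pairs as a random block, chosen after seeing the data, 4 of the 9 passed: AT2G36480 (limma adjusted p = 0.0119), AT2G46910 (0.0250), GH9B8 (0.0359) and AT3G09250 (0.0411). Over pair averages in other settings, AT2G46910 passed with the pair number as a block (0.0371), on the deposited scale (0.0115) and with median centring (0.0446), AT3G09250 with the pair number as a block (0.0416) and AT1G73740 with cyclic loess (0.0369). AT2G36480 had a log2 change of -2.83 (SE 0.50 over 16 arrays, 0.67 over pair averages; limma adjusted p = 0.0014 and 0.0957). AT3G09250 had a log2 change of -2.36 (SE 0.37 and 0.50; adjusted p = 0.00057 and 0.0560). AT2G46910, of the fibrillin family of plastid lipid-associated proteins, had a change of -2.80, or -2.19 with the common floor, at which 6 of 8 pete1 arrays lay (adjusted p = 0.00058 and 0.0545). AT4G33500, a protein phosphatase 2C family gene, had a change of -2.45, or -2.03 with the common floor, at which 6 of 8 pete1 arrays lay (adjusted p = 0.0134 and 0.1203). AT4G27250 had a change of 1.90 (SE 0.43 and 0.57; adjusted p = 0.0082 and 0.184).

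In the remaining rises part or all of the WT arrays lay at the common floor (5 of 8 for AT5G64150 and AT4G08280, 8 for GH9B8 and 7 for AT1G73740), so their fitted size depends on the floor. For GH9B8 and AT1G73740, 2 of 8 pete1 arrays lay there too. AT1G73740 was at the array's own floor on pete1 replicates 2 and 8 (-4.24 and -5.08, against a WT mean of -5.18). It thus met the rule of 7 of 8 arrays through these floors. With the common floor, AT5G64150 had a log2 change of 1.57 in place of 2.68, the glycosyl hydrolase GH9B8 1.11 in place of 2.43, and AT4G08280 1.22 in place of 2.17. AT1G73740 had 1.24 in place of 2.19, and its adjusted p of 0.0180 became 0.154. The pair averages of AT5G64150 and AT4G08280 overlapped between the groups: AT5G64150 was -1.31 and -1.73 on WT replicates 7 and 8, against a pete1 mean of -1.83.

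**Figure D1:**
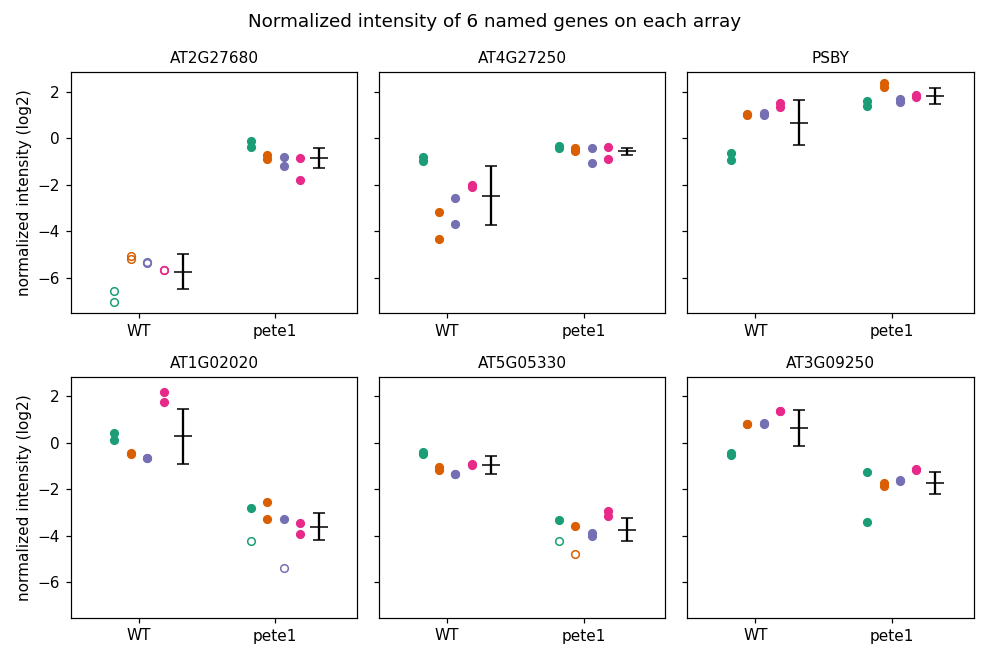
Normalized intensity (log2) of 6 of the named genes in WT and pete1. Each point is an array, the colour marks the array pair, open points lie at the array's floor, and the black bar is the mean ± SD of 4 pair averages. AT2G27680 is at the floor on 8 of 8 WT arrays, and AT1G02020 and AT5G05330 are lower on all 8 pete1 arrays than on any WT array.

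The fixed lists hold genes for photosynthesis, other plastid functions and stress, and markers of other organs or cell types. Of their genes 20 of 329 were measured, in 10 of 22 lists. Over 16 arrays 1 of these 20 rose, 0 fell and 19 did not pass. Over pair averages 0 passed, and 1 had an unadjusted limma p under 0.05. Adjusted over the 20 measured genes of all lists together, 0 passed over 16 arrays. Of the 3 photosystem II genes, PSBY rose by 1.13 on the log2 scale over 16 arrays, from 0.67 ± 0.99 to 1.81 ± 0.34 (SD, n = 4; limma adjusted p = 0.0413 over 16 arrays, 0.0136 adjusted over the list alone and 0.312 over pair averages). PSB27, a photosystem II assembly factor, had a log2 change of -0.90 (adjusted p = 0.1002), and PSBW one of 0.78 (adjusted p = 0.142). PSAN of photosystem I had a change of 0.56 (adjusted p = 0.271). The light-harvesting gene LHCB1.5, whose probe may also bind close copies, had a change of 1.16 (SE 0.68; adjusted p = 0.231).

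In the Calvin cycle list, phosphoribulokinase PRK had a change of -0.35 (adjusted p = 0.639), and SBPASE, at the common floor on 8 WT and 7 pete1 arrays, has no measurable fold. The SBPASE probe is also the 1 of 2 members counted as passing when adjusted over the list alone. The chlorophyll synthesis genes CHLP and CHLM had changes of 0.61 and -0.48 (adjusted p = 0.112 and 0.247). NTRC and FTRB of the thioredoxin system had changes of 0.67 and 0.62 (adjusted p = 0.0831 and 0.401), and the copper chaperone CCS one of -0.61 (adjusted p = 0.138). The changes of PRXIIE (0.22) and FATB (0.62) did not pass the test (adjusted p = 0.773 and 0.564) and turned sign with the scaling.

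The plastid ribosome was the 1 list with 5 or more measured members. Of its 6 members 0 passed the test, also when adjusted over the list alone. PRPL29 had a log2 change of -0.76 (adjusted p = 0.0746; 0.0454 with cyclic loess and 0.0440 with the exact Wilcoxon test), and PRPS6 lay at the common floor on 8 WT and 7 pete1 arrays. The list did not pass camera (p = 0.565), camera with an estimated correlation (p = 0.579) or fry (p = 0.931).

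Over all 16 arrays 464 of 3439 probes passed the limma test, 283 higher and 181 lower in pete1. Among probes naming 1 gene these were 99 of 692, 61 higher and 38 lower. Over 8 pair averages 9 probes passed, 5 higher and 4 lower, and all 9 are among the 464; 544 had an unadjusted p under 0.05. Without pete1 replicate 5 the fit over arrays called 878 probes, and leaving out 1 pair took the 9 to between 5 (without pete1 replicates 3 and 4) and 22 (without WT replicates 7 and 8). In 1 simulated data set with the correlation between consecutive arrays seen here, 37.9% of the calls of the fit over 16 arrays were false, against 4.80% over pair averages. These shares depend on the 200 probes changed there and on the lack of floors, and are not the false shares of the real calls. With the common floor 373 probes passed over 16 arrays, 190 higher and 183 lower, and 35 over pair averages, 17 higher and 18 lower. Leaving out 1 pair took the 35 to between 2 (without WT replicates 3 and 4, or 5 and 6) and 65 (without WT replicates 1 and 2). Some of the probes gained over pair averages had no array at the common floor and an unchanged log2 change. Their gain came through the other probes in the fit, of which 208 are constant with the common floor. A fit without these was not run. In 334 probes (9.71%) the pair averages of the groups did not overlap. Exchangeable pair averages would give 2.86% on average, but probes share the structure of the array pairs. How far this share varies over other splits was not computed.

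The excess of higher calls came with dim probes: of 105 called probes among the dimmest 25% of probes 104 were higher, and 6 of these stayed called with the common floor. The 464 calls include 9 of the 208 probes with no value above the common floor on any array, all 9 higher. The median probe shifted by 0.22 (log2) with quantile normalization, by 0.01 with the common floor and by -0.56 on the deposited scale, where 27 probes were called higher and 242 lower. The split was 168 higher and 186 lower with median centring, 169 and 199 with the 75th percentile, and 200 and 190 with cyclic loess. When 1 whole array pair was exchanged between the groups, the split of the 16 arrays gave up to 425 calls. With 2 pairs of each group on each side it gave up to 132. The split with 425 calls also parts the arrays with higher floors from those with lower ones.

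**Figure D2:**
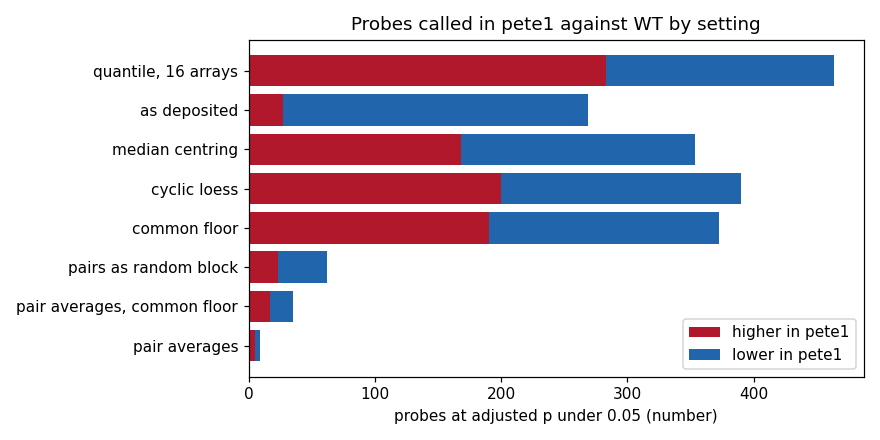
Number of probes at a limma adjusted p under 0.05 (horizontal axis) for 8 settings (vertical axis), split into probes higher and lower in pete1. The fit over 16 quantile-normalized arrays called 464 probes and the fit over 8 pair averages called 9, and on the deposited scale most calls were lower in pete1.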

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

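For each group of 8 arrays, the named genes and the array medians and shares of 0 were searched for a single array far from the rest. Of 54 groups of values 5 stood out, where chance gives about 1 in 20. On the log2 scale, AT1G73740 was -4.00 on WT replicate 1, with the next value at -5.08, and 0.52 on pete1 replicate 7, with the next at -2.43. AT4G33500 was -5.69 on WT replicate 8, the floor of that array, with the next value at -2.51. AT3G09250 was -3.39 on pete1 replicate 1, with the next at -1.87. PRXIIE was -6.90 on WT replicate 2, near that array's floor of -7.06, with the next at -4.44. No explanation was tested for these values.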

How the results depend on the processing

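The common floor, the random block, all combinations with pair averages, the local correction, the added lists and leaving out pairs or pete1 replicates 1 and 2 together were chosen after seeing the data; the other alternatives were planned. The cause was not tested except where stated. The 464 calls (283 higher, 181 lower) became 269 on the deposited scale (27 higher), 775 with the 1st percentile floor (579 higher), 762 with array weights (340 lower) and 875 with the exact Wilcoxon test (675 higher). The number higher was 168 with median centring, 169 with the 75th percentile, 173 with an offset, 185 and 160 with the dimmest 25% or 50% of probes left out (fewer probes tested), and 180 without pete1 replicates 1 and 2. Averaging pairs, which leaves fewer samples, gave 9 (5 higher, 4 lower), 7 on the deposited scale (2 and 5), 20 with median centring (8 and 12), 19 with cyclic loess (6 and 13), 35 with the common floor (17 and 18) and 16 with the pair number as a block (7 and 9). Pairs as a random block gave 62 (23 and 39). Leaving out 1 array gave 312 to 878 calls, 166 to 664 higher and 136 to 214 lower; without pete1 replicate 5 there were 878 (664 higher), and the number higher was 166, 178 and 184 without pete1 replicates 1, 3 and 4 and 188 without WT replicate 5. Leaving out 1 pair gave 5 to 22 calls over pair averages, and 2 to 65 with the common floor (2 to 23 higher, 0 to 42 lower), so the 35 calls depend on which pairs are used.

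The labels do not say what a shared replicate number means, so the numbers were not taken to pair the samples. Same-numbered WT and pete1 arrays deviate together with correlations of 0.0109 to 0.408, over 0.1 in 7 of 8. By these correlations 14 of 16 arrays match best with their own number. This comes from the data and not from the design, and it does not establish a pairing of single arrays. Within a group, odd-numbered arrays of different pairs are also more alike, as are even-numbered ones. For example, deviations correlate at 0.168 for WT replicates 3 and 5 and 0.195 for 4 and 6. They correlate at 0.066 for 3 and 6 and 0.050 for 4 and 5. With the replicate number as a block 494 probes were called, 271 higher and 223 lower.

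The plastid ribosome, the 1 fixed list tested, did not pass under any of 54 settings, with p from 0.292 to 0.950. Of the 13 named genes called over 16 arrays none changed direction. AT2G27680 stayed called in 54 of 54 settings, AT1G02020 and AT5G05330 in 48 of 55, and PSBY in 20 of 55. The 7 losses of AT1G02020 were all over pair averages with the common floor and 1 pair left out; those of AT5G05330 were all over pair averages, on the deposited scale (adjusted p = 0.0854), without pete1 replicates 3 and 4 and, with the common floor, in 5 of the fits with 1 pair left out. Among planned settings other than pair averages, PSBY lost its call in 10 (on the deposited scale, without WT replicate 1, 2 or 5 and without pete1 replicate 1, 3, 4, 6, 7 or 8), AT1G73740 in 4, AT5G64150 in 2 and GH9B8 in 1. Calls were gained by PRPL29 with cyclic loess (adjusted p = 0.0454) and the exact Wilcoxon test (0.0440), by PSAN (0.0273) and NTRC (0.0088) with array weights, and by CHLM (0.0024) and CCS (0.0055) with the local correction. Direction reversed for 3 genes that were not called. PRXIIE was -0.92 on the deposited scale (with pairs averaged too), -0.45 with median centring (with pairs averaged too), -0.48 with the 75th percentile, -0.23 with cyclic loess (with pairs averaged too), -0.0069 with the 1st percentile floor, -0.26 with an offset, -0.12 with array weights, -0.095 with the common floor without pete1 replicates 1 and 2, and -0.052 with the local correction. FATB was -0.57, -0.099 and -0.13 with the deposited scale, median centring and the 75th percentile, the first 2 with pairs averaged too. With an array or pair left out, PRXIIE ran from -0.15 to 0.47, FATB from -0.21 to 1.001 and PRK from -0.73 to 0.23. Values at 0 and the differing floors limit what dim probes can show.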

Other observations

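The gene lists and the genes of the next 2 paragraphs, the tests of the array pairs, of 1 floor for all arrays and of the deposited scale were chosen after the values they concern had been seen. Before the test along the probe order was written, bright probes 12 numbers apart with like profiles had been noticed, and before its WT part was written the pattern in the fold changes was known.

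With the common floor, 10 probes naming 1 gene passed over pair averages. The calmodulin-like gene CML41 rose by 1.42 on the log2 scale (limma adjusted p = 0.0101), and OTP70, an organelle transcript processing gene, rose by 1.499 (adjusted p = 0.0460). AT1G35510 rose by 1.05, AT1G79480 by 0.87 and AT3G02030 by 0.90 (adjusted p = 0.0217, 0.0406 and 0.0426). AT3G44570 fell by 1.44 and AT3G25840 by 1.83 (adjusted p = 0.0330 and 0.0423). AT2G27680, AT5G05330 and AT1G02020 are the other 3. Of the 10, only these 3 passed over pair averages with the floor of each array; adjusted p was 0.158 for CML41, 0.156 for OTP70, 0.262 for AT1G35510, 0.312 for AT1G79480, 0.207 for AT3G02030, 0.166 for AT3G44570 and 0.0728 for AT3G25840, and AT1G35510 did not pass over 16 arrays either (0.0690). Leaving out 1 pair took the 35 calls of this setting to between 2 and 65. CML41, OTP70, AT1G79480 and AT3G44570 had no array at the common floor and the same log2 change in both settings. Their lower adjusted p thus came through the other probes in the fit and not from their own values. In this setting 208 probes have the same value on all arrays, and limma's eBayes uses the spread of all probes. With unchanged values, the SE over pair averages went from 0.45 to 0.32 for CHLP and from 0.67 to 0.78 for AT2G36480. A fit without the constant probes was not run, so these calls may depend on them.

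Of 4 added lists none passed camera (adjusted p = 0.601, 0.675, 0.601 and 0.478 for photosynthesis genes together, thylakoid complex assembly, PPR and mTERF genes, and fibrillins). Over 16 arrays, 1 of 7 photosynthesis genes rose and 0 fell, 0 of 12 assembly genes rose and 1 fell, 1 of 22 PPR and mTERF genes rose and 0 fell, and 1 of 5 fibrillins rose and 1 fell. The directional fry p over 16 arrays was 0.0038 for the photosynthesis genes, 0.0885 for assembly, 9.0e-05 for PPR and mTERF genes and 0.0344 for fibrillins. These p-values treat the correlated consecutive arrays as independent. The fry test was not run over pair averages, where 0 members of each added list passed the limma test. The fry test does not compare a list with other genes, and the floors raise dim members. CCS1 of the assembly list and the PPR gene AT4G14050 both had a change of 0.84, equal to the difference in mean floor. SBPASE of the photosynthesis genes lay at the common floor on 8 WT and 7 pete1 arrays. Such members are counted in the lists without a measurable change, and no list test without them was run. Within the lists PAC fell by 1.48 (limma adjusted p = 0.0014 over 16 arrays and 0.179 over pair averages), FIB5 rose by 1.45 (0.0410 and 0.269), and the fibrillin AT2G46910 fell by 2.80 (0.00058 and 0.0545).

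The fit over 16 arrays called 464 probes and the fit over pair averages 9. In 100 drawn splits of the 16 arrays, 1 (the real one) gave as many calls, and the highest of the others gave 92, a split made of whole pairs; most drawn splits part the correlated arrays of a pair and so give few calls, and this share decides nothing. In the 35 splits that keep pairs together, 1 gave as many; the others had a median of 3 calls, 6 gave over 100, and the highest gave 425, with 1 pair exchanged between the groups. A share of 1 in 35 is the smallest these splits can give, and the 425 calls point to a structure of the array pairs. The splits also treat all pairs as exchangeable, though same-numbered WT and pete1 arrays deviate together. They therefore do not exclude chance. Over pair averages 1 of 35 splits gave as many as the real 9 (highest other 1), and 1 of 35 as many as the real 35 with the common floor (highest other 1). A candidate explanation is that consecutive arrays are repeats of one hybridisation: their deviations correlate at a median of 0.439, but arrays of shared plants would do so too, the labels do not say, and these cannot be told apart.

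Fold changes of probes at a fixed distance in probe number go together. Over distances of 1 to 24 the highest correlation was 0.176, at 12, against 0.0787 in 1000 shuffles; at multiples of 6 it was 0.133 to 0.176 and elsewhere at most 0.0677. Signal shared along the printed order may account for it. On WT arrays alone, deviations at distance 6 correlate at a median of 0.259. This value by itself is not specific, because WT deviations correlate by at least 0.133 at every distance tested. At multiples of 6 they are higher than beside them, which argues against the genotype as the whole cause. The medians were 0.259 at distance 6 against 0.215 at 5 and 0.225 at 7. At distance 12 they were 0.270 against 0.184 at 11 and 0.180 at 13. The WT correlations were not computed with the common floor. WT deviations also correlate at the other distances tested (0.286 at distance 1), where fold changes correlate far less. The common floor lowered the correlation at 6 to 0.111. With the local correction 514 probes were called, of which 309 are among the 464.

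Dim probes were called almost always as higher in pete1 (104 of 105). The arrays' own floors may be the cause. The mean floor is 0.84 higher (log2) in pete1, and the median change of the dimmest 25% of probes is the same 0.84. In 33 of the 34 other splits of the pair averages the median dim probe moved with the sign of the floor difference. Because 69.4% of dim values lie at a floor, both matches follow in part from the processing and are no separate evidence. On all 16 arrays 208 probes had no value above the common floor. With the floor of each array, 196 of these had an unadjusted limma p under 0.05 over 16 arrays, and 9 were called, all higher. With 1 floor 6 of the 104 stayed called, though that floor also hides real dim signal, and a genotype effect on dim genes stays open. On the deposited scale the median probe of the 4 pete1 pairs shifted by -1.66, -1.08, 0.13 and 0.19 against WT, a range of 1.85, with 23.96%, 18.6%, 16.2% and 18.1% of values at 0, so the shift does not follow the share of 0 values throughout. The values are read as relative to the brightest spots. An effect of this scaling is a candidate explanation and cannot be told apart from a change in the samples, because the details of the scaling are not given in the sources used here.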
